A study of Homo sapiens with 24 samples.

How the data were processed

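The samples were 24 polyA RNA libraries of SKBR3 cells, a human breast carcinoma line with amplified ERBB2, the gene of the receptor HER2. There were 3 groups of 8 libraries: untreated cells (control), cells given Herceptin (trastuzumab, a monoclonal antibody that binds HER2) and cells given a biosimilar of it, named ApoTras in the labels' protocols. Per the labels' protocols, cells were seeded at 6500 per cm2 in medium with 10% fetal bovine serum, the medium was changed on days 1 and 4, the antibodies were given in phosphate-buffered saline and RNA was extracted on day 7. The labels give a dose of 4 µg/ml beside Herceptin and do not clearly state that it applies to the biosimilar as well. Libraries were made with the TruSeq Stranded mRNA kit and read as 126-base paired ends, also per the labels' protocols. No vehicle-only group, unrelated antibody, plate or sequencing batch is given in the labels.

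The deposited values were expected counts per gene, which RSEM estimates by dividing reads that map to several places, so that a count need not be whole. Per the submitters' processing notes the reads were checked with FastQC, aligned with STAR and counted with RSEM on GRCh38.p12. The annotation release, trimming, the strand setting and the RSEM settings are not given in the sources used here. Of the deposited expected counts, 9.29% were not whole. A gene whose counts were not whole in most libraries shares reads with a similar sequence and is named below as uncertain.

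The deposited table held 60617 rows. Expected counts were rounded to whole numbers, which moved a library's total by at most 4.6e-04%. Genes with too few counts were left out by edgeR's filterByExpr with the groups, leaving 13536. Of these, 12403 had a deposited symbol, 476 were named from a list of gene names and 657 had none. There were 15 tested rows identical to another row, among them copies of the 5.8S ribosomal RNA gene. Library totals ran from 9070186 to 12260086 expected counts, and the common biological coefficient of variation was 4.9%. Counts of the 84 pairs of libraries within groups differed by more than sampling noise, with a chi-square per degree of freedom between 1.515 and 7.912, so that each library was counted as a separate replicate. The labels name 8 replicates per group but nothing says that they were separate cultures or how they were batched, so that p-values measure only the spread between these libraries, which may be technical.

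All 24 libraries were fitted in 1 model with 3 groups in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with TMM factors, estimated dispersions, robust quasi-likelihood fits and the quasi-likelihood F test, which takes changes in either direction. Adjusted p-values are Benjamini-Hochberg values over the 13536 genes of a comparison, with a threshold of 0.05. Fold changes used a prior count of 0.125. CPM values used the TMM-scaled totals. Whether the biosimilar and Herceptin differed by less than 1.5-fold was tested per gene with a pair of one-sided tests (90% interval) and the same adjustment. Gene coordinates and types are from GENCODE release v29 on GRCh38, in which 99.51% of the tested genes were found. Mitochondrial genes were taken by chromosome from that annotation.

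There were 29 gene lists, tested with camera on log2 CPM with an inter-gene correlation of 0.01, and again with an estimated correlation and with fry. fry tests whether the genes of a list move in a common direction on balance and does not compare the list with other genes. Each list's p was adjusted over the lists of its comparison. The lists, the main tests and the rule for named genes were fixed before the data were examined. The rule takes, for each antibody against control, the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM, a symbol that is not a clone name and all 8 treated libraries on the same side of the control median. For the biosimilar against Herceptin it takes 5 of each by the same rule or, where none pass, the 3 smallest p in each direction, of which 1 gene is not reported here. ERBB2, EGFR and ERBB3 are always named, as are up to 3 members with the smallest p of each list.

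The model was tested on simulated counts of 13536 genes with 200 changed genes. For the biosimilar against Herceptin it recovered 65.6% of genes changed 1.2-fold, 88% of those changed 1.5-fold and 98.4% of those changed 2-fold, and 6.11% of its calls were false. These rates hold for 200 changed genes, which gave 180 calls. With fewer changed genes the adjusted threshold is stricter, so that the rates may overstate what the real comparison could detect. Other settings tried were DESeq2 1.42.0, limma-voom, a surrogate variable from sva 3.50.0, other scaling factors, other filters, a replicate block, thresholds on the size of change and leaving out each library in turn. Chosen after seeing the data were thinning all libraries to the smallest total and leaving out the 20 most abundant and the mitochondrially encoded genes. Figures were drawn with matplotlib 3.10.9.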

Results

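RNA abundance was measured in SKBR3 cells on day 7 in 8 untreated, 8 Herceptin-treated and 8 biosimilar-treated libraries, to assess how similar the biosimilar is to Herceptin by the mRNAs of treated cells. Library totals averaged 9982334 expected counts in control (9116591 to 10759115), 11489206 with Herceptin (10747837 to 12260086) and 10271053 with the biosimilar (9070186 to 11880165). The groups thus differed somewhat in depth, and CPM values were scaled for it.

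ERBB2, which encodes the receptor that both antibodies bind, rose slightly with each of them. The gene lies on chromosome 17 from 39687914 to 39730426 (GRCh38, protein-coding, counted over its transcripts). Its level was 4174 ± 116 CPM in control (SD, n = 8), 4512 ± 93.1 with Herceptin and 4563 ± 158 with the biosimilar, a log2 fold change of 0.11 (SE 0.0244, edgeR adjusted p = 1.92e-04) and 0.13 (SE 0.0244, adjusted p = 2.92e-05), with all 8 libraries of each antibody above the control median. Its expected counts were not whole in 100% of libraries, and those of EGFR in 54.2%, so that some of their reads were shared with other sequences and both values are uncertain to that extent. The related receptor genes ERBB3 and EGFR rose more: ERBB3, whose product pairs with HER2, went from 159.9 ± 5.47 to 216.1 ± 4.12 CPM with Herceptin and 214.6 ± 10.7 with the biosimilar, and EGFR from 168.2 ± 6.28 to 222.8 ± 6.6 and 222.4 ± 21.4, with biosimilar replicate 6 at 176.2 and the others at 211.5 to 246. EGF, which encodes a ligand of EGFR, rose by 0.39 on the log2 scale (SE 0.0535) with Herceptin and by 0.46 (SE 0.0539) with the biosimilar. Of 7 tested genes of the HER receptors and their ligands, 5 rose and 0 fell with either antibody. The list passed camera with Herceptin (adjusted p = 0.00117, and adjusted p = 0.0315 with an estimated correlation) and with the biosimilar (adjusted p = 0.00168, and adjusted p = 0.0482 with an estimated correlation).

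**Figure D1:**
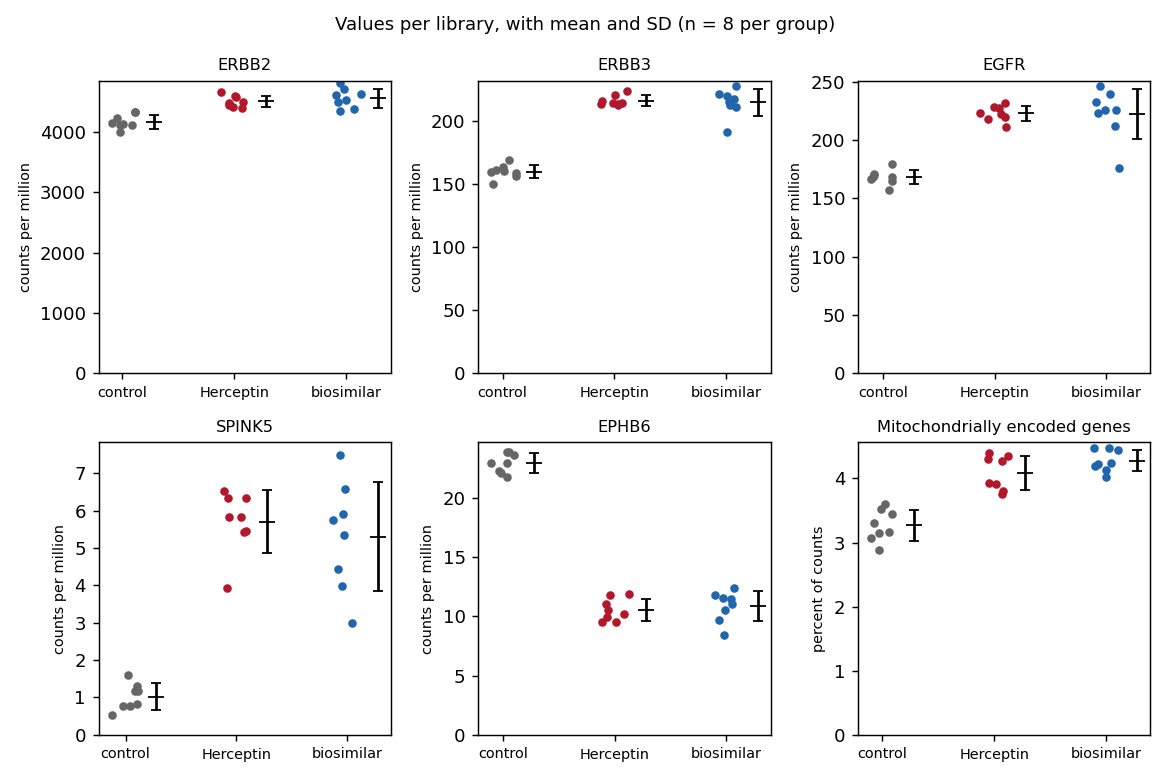
Values of each library in CPM for ERBB2, ERBB3, EGFR, SPINK5 and EPHB6 and, in the last panel, the percent of counts from mitochondrially encoded genes, by group. Points are libraries, bars are the mean and SD of 8 libraries, and the ERBB2 means are 4174, 4512 and 4563 CPM in control, Herceptin and biosimilar libraries.

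Against untreated cells, SPINK5, which encodes a protease inhibitor of the epidermis (chromosome 5, 148025683 to 148137289), had the largest rise with Herceptin among the genes that the naming rule admits, from 1.019 ± 0.361 to 5.706 ± 0.832 CPM (SD, n = 8; log2 fold change 2.46, SE 0.185, edgeR adjusted p = 8.46e-14, all 8 libraries above the control median). Next came LCE3D, PRR9 and SPRR1B, genes of the cornified envelope cluster on chromosome 1, with log2 fold changes of 2.13 (SE 0.318), 2.05 (SE 0.235) and 1.94 (SE 0.211) at control levels under 1 CPM. The Notch ligand gene DLL4 rose from 1.942 ± 0.356 to 7.133 ± 0.633 CPM. The other large rises were in MME, KRT27, CDSN, ECM1 and ADGRF1, with log2 fold changes from 1.82 down to 1.55. ADGRF1, which encodes an adhesion G-protein-coupled receptor, was the most abundant of them, at 10.66 ± 0.851 CPM in control and 31.32 ± 2.61 with Herceptin. CDSN is uncertain, since its counts were not whole in 79.2% of libraries.

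The largest falls with Herceptin included EPHB6, an Eph receptor gene on chromosome 7 (142855061 to 142871094), which went from 22.95 ± 0.832 to 10.56 ± 0.947 CPM (log2 fold change -1.12, SE 0.0612, edgeR adjusted p = 2.47e-18, 0 of 8 libraries above the control median). STAC2 went from 27.44 ± 3.74 to 13.21 ± 1.7 CPM and GABRQ, a GABA receptor subunit gene, from 11.98 ± 0.913 to 5.648 ± 0.505. KCNH2, a potassium channel gene, GPRIN3 and KCTD12 fell by 1.31, 1.12 and 1.09 on the log2 scale. KCNH2 was low, at 1.591 ± 0.508 CPM in control and 0.6311 ± 0.192 with Herceptin, and fell by 0.64 (SE 0.221) with the biosimilar. Its difference between the antibodies did not pass (0.67, SE 0.255, edgeR adjusted p = 0.893) and was not bounded within 1.5-fold. KREMEN2, RPL39P3, RPS2P46 and MICOS10-NBL1 also fell but are uncertain: the middle pair are pseudogenes, the last is a readthrough gene, and their counts were not whole in between 91.7% and 100% of libraries.

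In all, 6283 of 13536 tested genes changed with Herceptin (edgeR), of which 3068 rose and 3215 fell. Most changes were small: 57.1% of the changed genes differed by under 1.2-fold, and 104 rose and 16 fell by at least 2-fold. Tested against a 1.2-fold change in place of 0, 1079 genes passed.

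Genes of cell division fell with both antibodies. For each list, counts of risen or fallen members adjusted over the list alone differed by at most 1 from those over all genes tested with Herceptin and by at most 3 with the biosimilar. Of 42 tested genes of G2/M and mitosis, 40 fell and 0 rose with Herceptin, and the same counts held with the biosimilar (camera adjusted p = 1.77e-21 and 1.53e-20, and adjusted p = 0.00124 and 0.00159 with an estimated correlation). CCNA2, the cyclin A2 gene, went from 128.8 CPM in control to 94.21 with Herceptin and 93.89 with the biosimilar, and BIRC5 from 118.9 to 86.01 and 85.72. Of 43 genes of G1/S and DNA replication, 41 fell with Herceptin and 38 with the biosimilar (42 and 39 adjusted over the list alone), and 0 rose (camera adjusted p = 2.89e-16 and 8.3e-16, and adjusted p = 6.38e-04 and 7.67e-04 with an estimated correlation). RRM2, a subunit gene of ribonucleotide reductase, fell by 0.41 (SE 0.0274) and 0.40 (SE 0.0275) on the log2 scale, and CDC25A by 0.48 (SE 0.0375) and 0.52 (SE 0.0383). Among 6 tested genes of CDK inhibitors, CDKN2B rose from 17.26 to 29.1 and 28.37 CPM, while 3 fell with Herceptin and 4 with the biosimilar, and the list did not pass (adjusted p = 0.802 and 0.742). Ribosome biogenesis genes were lower as well: 19 of 33 fell with Herceptin and 22 with the biosimilar, with 0 and 1 rising, among them MRTO4 and NOP56 (camera adjusted p = 2.44e-04 and 3.92e-04, and adjusted p = 0.0248 and 0.0304 with an estimated correlation).

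Target genes of the FOXO transcription factors rose. Of 25 tested, 17 rose and 1 fell with Herceptin, and 18 rose and 1 fell with the biosimilar (camera adjusted p = 1.65e-10 and 4.71e-10, and adjusted p = 8.68e-04 and 0.00114 with an estimated correlation). FBXO32, a ubiquitin ligase gene, went from 90.52 CPM in control to 193.8 with Herceptin and 190.6 with the biosimilar, log2 fold changes of 1.10 (SE 0.0321) and 1.07 (SE 0.0322). TXNIP went from 81.7 to 151.4 and 152.8 CPM, and CITED2 from 97.09 to 155.5 and 150.8. Autophagy and lysosome genes rose too, 26 of 33 with either antibody (27 adjusted over the list alone) and 1 falling (camera adjusted p = 7e-12 and 4.39e-11, and adjusted p = 0.0015 and 0.0022 with an estimated correlation). CTSA and CTSL, which encode lysosomal cathepsins, rose by 0.43 (SE 0.027) and 0.48 (SE 0.0336) on the log2 scale with Herceptin and by 0.43 (SE 0.0271) and 0.43 (SE 0.0338) with the biosimilar.

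**Figure D2:**
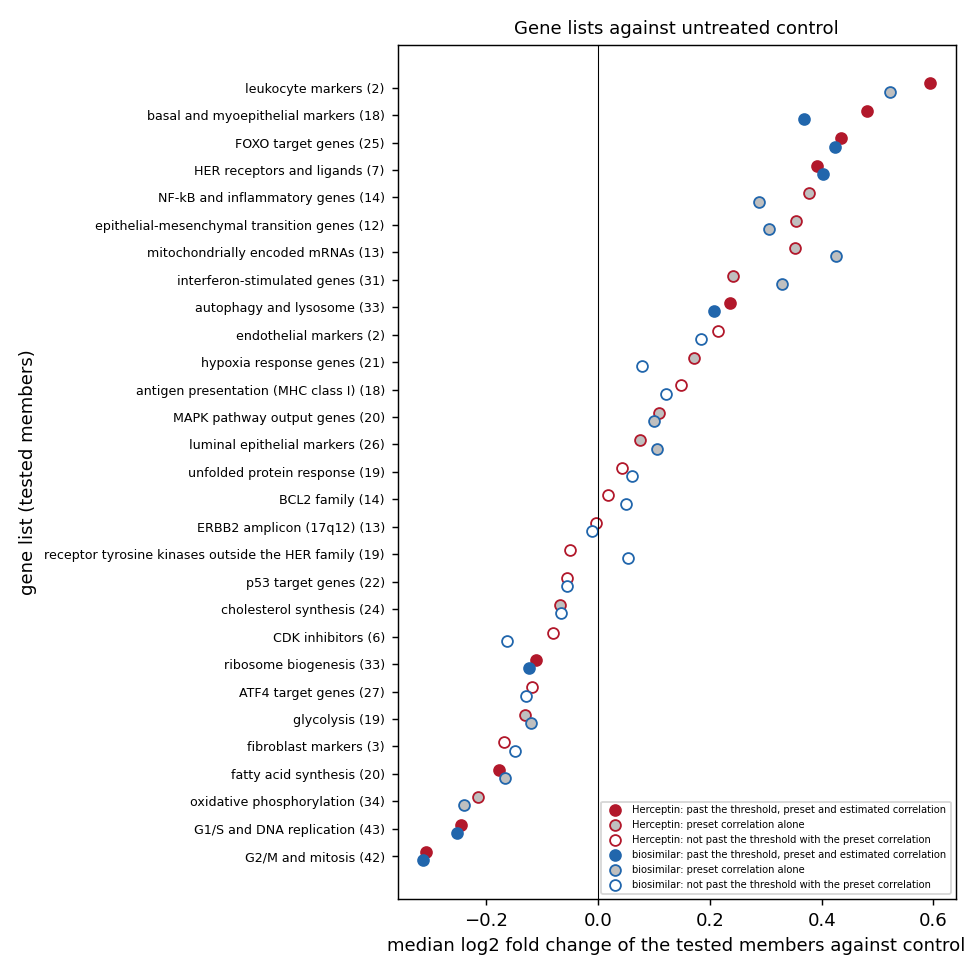
Median log2 fold change against control of the tested members of each gene list, in red for Herceptin and blue for the biosimilar, with the number of tested members in brackets. Red or blue points passed camera with the preset and with the estimated correlation, grey points with the preset one alone and open points with neither, and the G2/M and mitosis list is lowest, at -0.307 with Herceptin and -0.313 with the biosimilar.

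Mitochondrially encoded mRNAs were higher while nuclear genes of oxidative phosphorylation were lower. Of the 13 mitochondrial mRNAs, 12 rose with either antibody (camera adjusted p = 6.8e-06 with Herceptin and 1.03e-06 with the biosimilar, but adjusted p = 0.197 and 0.17 with an estimated correlation). ND4 went from 3813 CPM to 5324 with Herceptin and 5661 with the biosimilar. All mitochondrially encoded genes together held 3.266% ± 0.247 of counts in control (SD, n = 8), 4.087% ± 0.264 with Herceptin and 4.277% ± 0.169 with the biosimilar. Each antibody differed from control at an exact two-sided permutation p of 1.55e-04, the smallest that 12870 regroupings of 16 libraries can give, while a difference between the biosimilar and Herceptin was not detected (0.19 percentage points, exact permutation p = 0.11). This share includes 2 ribosomal RNAs. The 13 mRNAs alone held 2.51% ± 0.2 of counts in control, 3.19% ± 0.227 with Herceptin and 3.39% ± 0.136 with the biosimilar, and were not permuted. Of 34 nuclear oxidative phosphorylation genes, 28 fell and 2 rose with Herceptin, and 29 fell and 3 rose with the biosimilar (camera adjusted p = 4.83e-09 and 5e-09, but adjusted p = 0.106 and 0.124 with an estimated correlation). ATP5F1B, an ATP synthase subunit gene, fell by 0.32 (SE 0.0242) and 0.31 (SE 0.0242) on the log2 scale, and CYC1 by 0.40 (SE 0.0314) and 0.40 (SE 0.0316). Tested genes of at most 982 bases were also examined, without ribosomal proteins, this list and other genes named as oxidative phosphorylation subunits. Mitochondrially encoded genes and short nuclear ribosomal RNA genes with a symbol were left out too. The remaining 1208 short genes had a median log2 fold change of -0.05 with Herceptin and -0.10 with the biosimilar. Those of at least 10 CPM (572 genes, a limit chosen after the result was seen) were lower, at -0.11 and -0.16.

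Lipid and sugar metabolism genes fell in part. Of 20 fatty acid synthesis genes, 12 fell with Herceptin and 11 with the biosimilar, and 2 rose (camera adjusted p = 0.00305 and 0.0159, and adjusted p = 0.0315 and 0.0832 with an estimated correlation). SREBF1, a transcription factor gene of lipid synthesis, went from 582.3 to 467.8 and 466.4 CPM. Of 24 cholesterol synthesis genes, 12 fell and 3 rose with either antibody (camera adjusted p = 0.0323 with Herceptin and 0.0619 with the biosimilar, and adjusted p = 0.197 and 0.259 with an estimated correlation), FDPS among the falls. Of 19 glycolysis genes, 11 fell with Herceptin and 12 with the biosimilar, and 3 rose, with TPI1 lower and HK2 higher (camera adjusted p = 0.0246 and 0.0221, but adjusted p = 0.26 and 0.259 with an estimated correlation).

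Basal and myoepithelial markers rose, 14 of 18 with either antibody and 0 falling (camera adjusted p = 8.28e-07 and 3.89e-05, and adjusted p = 0.00337 and 0.0146 with an estimated correlation). CD44, an adhesion receptor gene, went from 12.63 CPM to 25.53 with Herceptin and 23.62 with the biosimilar, and ITGB4 from 53.21 to 77.3 and 76.82. Of 26 luminal epithelial markers, 13 rose with either antibody, and 4 fell with Herceptin and 5 with the biosimilar, with MLPH and EHF higher (camera adjusted p = 0.0141 and 0.0216, but adjusted p = 0.0704 and 0.0924 with an estimated correlation). Of 12 epithelial-mesenchymal transition genes, 8 rose and 3 fell with either antibody, TGFBI among the rises (camera adjusted p = 0.00305 and 0.013, but adjusted p = 0.0926 and 0.156 with an estimated correlation). Markers of other cells were mostly too low to test: 2 of 20 leukocyte, 3 of 13 fibroblast and 2 of 11 endothelial markers were tested. The 2 tested leukocyte markers, CD68 and CSF1R, rose with either antibody (camera adjusted p = 0.00433 and 0.0114, and adjusted p = 0.0315 and 0.0545 with an estimated correlation), CD68 from 18.43 to 32.04 and 29.89 CPM. Of 3 fibroblast markers, ACTA2 rose from 4.204 to 8.978 and 7.684 CPM, COL1A1 fell with both antibodies and COL5A1 fell with Herceptin. The log2 fold change of COL5A1 was -0.17 with Herceptin (SE 0.07, adjusted p = 0.0463) and -0.15 with the biosimilar (SE 0.0712, adjusted p = 0.0809). Over 12 alternatives its adjusted p with Herceptin ran from 0.0266 to 0.105, and 5 lost the call. The list did not pass (adjusted p = 0.907 and 0.968), its median below 0 and its mean above. Of 2 endothelial markers CDH5 rose, ESAM had log2 fold changes of -0.012 (SE 0.0595) and -0.0059 (SE 0.0605), and the list did not pass (adjusted p = 0.233 and 0.279).

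Interferon-stimulated genes rose in part, 15 of 31 with Herceptin and 17 with the biosimilar, with 1 falling, USP18 (camera adjusted p = 7.87e-04 and 5.63e-04, but adjusted p = 0.26 and 0.259 with an estimated correlation). IRF1 went from 23.36 CPM to 32.84 and 31.27. Of 14 NF-kB and inflammatory genes, 10 rose with Herceptin and 9 with the biosimilar, LCN2 and CCL2 among them, and 1 fell (camera adjusted p = 0.00332 and 0.00934, but adjusted p = 0.0514 and 0.0832 with an estimated correlation). Of 20 output genes of the MAPK pathway, 11 rose and 3 fell with Herceptin, and 10 rose and 2 fell with the biosimilar (camera adjusted p = 0.0186 and 0.0354, but adjusted p = 0.0926 and 0.143 with an estimated correlation). EGR1, an immediate-early gene, went from 10.89 to 23.56 and 23.72 CPM. Of 21 hypoxia response genes, 12 rose and 5 fell with Herceptin, and 10 rose and 6 fell with the biosimilar, HILPDA and NDRG1 rising with both (camera adjusted p = 0.0309 and 0.177, and adjusted p = 0.195 and 0.373 with an estimated correlation).

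The other lists did not pass camera with either antibody, and their members moved in both directions. Of 27 ATF4 target genes, 12 fell with either antibody while 5 rose with Herceptin and 6 with the biosimilar, with PSAT1, a serine synthesis gene, lower and PPP1R15A higher (adjusted p = 0.146 and 0.0802). Of 18 genes of antigen presentation 7 rose, ERAP1 and TAPBP among them, and 1 fell (adjusted p = 0.055 and 0.194). Of 19 receptor tyrosine kinases outside the HER family, 7 rose and 8 fell with Herceptin, and 5 rose and 7 fell with the biosimilar, with INSR higher and EPHB6 and FGFR1 lower (adjusted p = 0.746 and 0.774), and with the biosimilar the median was above 0 and the mean below. Of 14 BCL2 family genes 5 rose and 3 fell, MCL1 up and BAK1 down (adjusted p = 0.781 and 0.852). Of 22 p53 targets, 3 rose with Herceptin and 5 with the biosimilar, and 7 fell, AEN lower and XPC higher (adjusted p = 0.622 and 0.774). Of 19 unfolded protein response genes, 6 rose with Herceptin and 9 with the biosimilar, and 5 fell, SDF2L1 among them (adjusted p = 0.771 and 0.506), and with Herceptin the median was above 0 and the mean below. Of 13 genes of the ERBB2 amplicon, 2 rose with Herceptin and 3 with the biosimilar, and 4 fell, GRB7 higher and STARD3 lower (adjusted p = 0.89 and 0.852).

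With the biosimilar, SPINK5 again had the largest rise against untreated cells among the genes that the naming rule admits (5.303 ± 1.45 CPM against 1.019 ± 0.361 in control, SD, n = 8; log2 fold change 2.37, SE 0.189, edgeR adjusted p = 4.4e-13, all 8 libraries above the control median). LCE3D, KRT27, PRR9, DLL4, SPRR1B and MME also rose, with log2 fold changes from 1.90 down to 1.54. KRT20, a keratin gene, rose from 0.6367 ± 0.339 to 1.947 ± 0.354 CPM. FAM156B and KRIT1 also passed the rule but are uncertain: their counts were not whole in 91.7% and 87.5% of libraries, and over the alternatives run the adjusted p of FAM156B ran from 0.00768 to 0.0516, lost with DESeq2, and that of KRIT1 from 0.00245 to 0.0819, lost with DESeq2, limma-voom and no filter on low counts. Among the falls, GPRIN3 went from 3.03 ± 0.502 to 1.185 ± 0.271 CPM and KANK4 from 2.024 ± 0.662 to 0.8626 ± 0.316. The other largest falls are uncertain for shared reads: RPL39P3, RPS2P46, MICOS10-NBL1, CENPS-CORT, KREMEN2 and identical copies of 5.8S ribosomal RNA genes (5_8S_rRNA, RNA5-8SN1 and RNA5-8SN3), a transcript that polyA selection mostly removes. In all, 6495 of 13536 tested genes changed (edgeR), of which 3162 rose and 3333 fell. At least a 2-fold change was reached by 93 risen and 25 fallen genes, and 1197 genes passed a test against a 1.2-fold change.

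Of the genes that changed with the biosimilar, 5528 also changed with Herceptin, 967 passed with the biosimilar alone and 755 with Herceptin alone, and none of these passed in the direct comparison of the antibodies. With both antibodies 2694 genes rose and 2834 fell, and 0 rose with 1 antibody and fell with the other. Independent lists of these sizes would share 717 risen and 792 fallen genes. In simulations of unchanged groups, with simulated controls shared by both comparisons, 0 calls were shared. That says little about the overlap, since such groups had at most 1 call with Herceptin and 0 with the biosimilar. With the 8 controls divided so that each antibody had 4 of its own, 1972 genes rose and 2118 fell with both, and 4 went in opposite directions. Across genes, which are not independent replicates, the log2 fold changes of the antibodies had a Pearson r of 0.908. This r was 0.513 in the simulations of unchanged groups and 0.747 with the controls divided. The covariance was 0.0768 against a simulated 0.00781, a difference of 0.069.

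**Figure D3:**
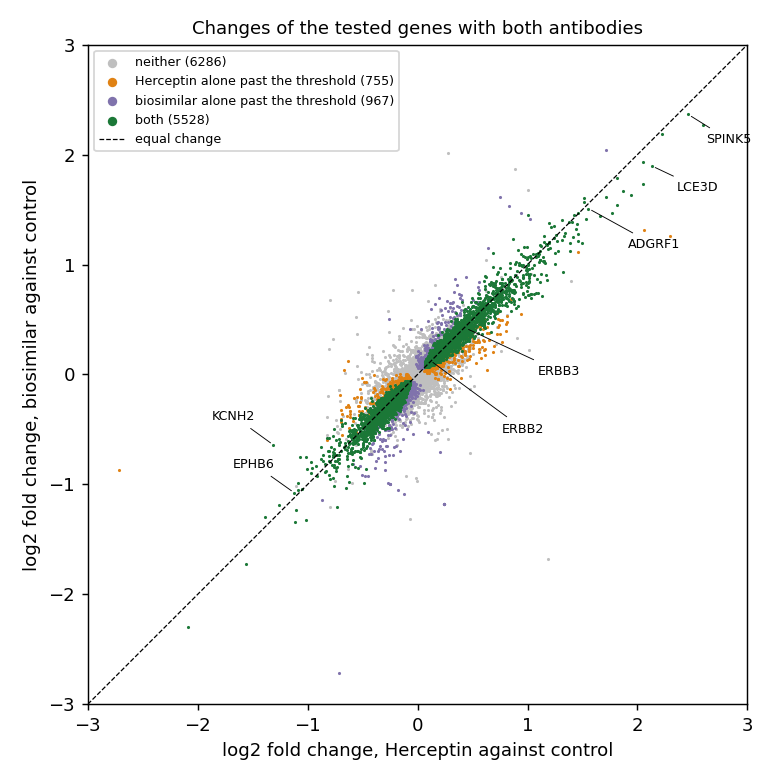
Log2 fold change against control of each of 13536 tested genes, with Herceptin on the horizontal and the biosimilar on the vertical axis. Colours mark genes past the adjusted threshold of 0.05 with both antibodies (5528), with Herceptin alone (755), with the biosimilar alone (967) or with neither (6286), the dashed line, along which the genes past it with both lie, marks equal change, and 1 gene lies outside the axes.

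The direct comparison asks whether the biosimilar differs from Herceptin at the doses given, which the labels do not clearly state to be equal. The log2 differences, biosimilar minus Herceptin, were 0.016 for ERBB2 (SE 0.0244, adjusted p = 0.984), -0.010 for ERBB3 (SE 0.0288, adjusted p = 0.989) and -0.0036 for EGFR (SE 0.0415, adjusted p = 0.996). SPINK5 stood at 5.706 ± 0.832 CPM with Herceptin and 5.303 ± 1.45 with the biosimilar (SD, n = 8; edgeR adjusted p = 0.982). In edgeR 0 of 13536 genes passed with the settings fixed beforehand. With the replicate number as a block 14 passed, of which 8 were copies of the 5.8S ribosomal RNA gene with identical counts, and with no filter on low counts 12. PFDN5, ATP5F1E and RPS26 passed in both and were lower with the biosimilar. With the fixed settings their log2 differences were -0.19 (SE 0.0512), -0.16 (SE 0.0515) and -0.16 (SE 0.039), and none passed. With the block, ATP5F1E and RPS26 had the same edgeR adjusted p as the 5.8S copies, 0.0366, and these copies were tested as separate genes. RPS26 is a short gene (648.41 bases), and short genes were lower as a class with the biosimilar, as described below. ATP5F1E is uncertain, since its counts were not whole in 100% of libraries. At an unadjusted p under 0.05 there were 722 genes, 5.33% of those tested, the smallest adjusted p was 0.273, and the median size of the log2 difference was 0.0414. limma-voom also called 0 genes and had 720 at an unadjusted p under 0.05, and DESeq2 called 8 (757 unadjusted), all with the identical counts of copies of the 5.8S ribosomal RNA gene. The difference was bounded within 1.5-fold for 12814 genes (94.67%) and within 2-fold for 13393 (98.94%). At the tightest margin tested, which lay between 1.2-fold and 1.5-fold, it was bounded for fewer, 10865 genes (80.27%), and not for 2671. The 722 genes not bounded within 1.5-fold were of low abundance, with a median of 1.22 CPM against 29.1 CPM for the bounded ones. Of the 7250 genes that changed with either antibody, 7045 (97.17%) were bounded within 1.5-fold. Most changes against control were themselves smaller than that: of 6283 genes changed with Herceptin, 420 rose and 132 fell by at least 1.5-fold. The share bounded within 1.5-fold therefore says little about whether the responses match.

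Genes with the smallest p in the direct comparison, none of which passed, included KIAA1324 and SLMAP on the higher side with the biosimilar and RPS26, BHLHE40 and 5_8S_rRNA on the lower side. KIAA1324 stood at 29.32 ± 1.75 CPM with Herceptin and 33.94 ± 1.37 with the biosimilar (SD, n = 8; log2 difference 0.21, SE 0.0466, edgeR adjusted p = 0.273), and BHLHE40 at 85.19 ± 2.82 and 76.81 ± 5.79 (log2 difference -0.15, SE 0.0371, adjusted p = 0.273). RPS26, BHLHE40 and 5_8S_rRNA are uncertain, with counts not whole in 100%, 66.7% and 100% of libraries. Of the 29 lists, 3 passed camera: hypoxia response genes were lower with the biosimilar (median log2 difference -0.04, adjusted p = 0.00568, but adjusted p = 0.332 with an estimated correlation), basal and myoepithelial markers were lower (median -0.08, adjusted p = 0.0146, but adjusted p = 0.332 with an estimated correlation) and mitochondrially encoded mRNAs were higher (median 0.06, adjusted p = 0.00568, but adjusted p = 0.925 with an estimated correlation). With fry 0 lists passed. Of the hypoxia response genes 2 fell adjusted over the list alone, of the epithelial-mesenchymal transition genes 1 fell and of the p53 targets 1 rose, against 0 over all genes tested. Median, mean and test differed in sign for the cholesterol synthesis, HER receptor and ligand, luminal marker and ERBB2 amplicon lists, none of which passed. Since the labels give no batches, a batch that follows the groups cannot be told apart from them, and the control libraries had no vehicle or unrelated antibody.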

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

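Tests chosen only after the result was seen were the exact permutation of the mitochondrial share, the bounds of the 1q21 cluster and the short-gene test restricted to genes of at least 10 CPM. Leaving out the libraries with the most extreme short-gene scores was planned. Both ways of choosing these libraries were settled only after the result was seen.

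Of 114 groups of 8 libraries examined for the named genes, 12 had a library far from the other 7, where chance gives about 1 in 20 (5.7 expected). The 12 count RNA5-8SN3, 5_8S_rRNA and RNA5-8SN1 separately although their counts are identical, so that the excess over chance is overstated. Herceptin replicate 8 was low for SPINK5 at 3.92 CPM (others 5.43 to 6.53) and high for PRR9 at 4.74 CPM (others 2.23 to 3.37). Control replicate 6 stood at 0.0988 CPM for SPRR1B, biosimilar replicate 2 at 26.6 CPM for ADGRF1 and Herceptin replicate 6 at 0.551 CPM for KANK4. Biosimilar replicate 3 stood at 1.79 CPM for GPRIN3 and 63.4 CPM for BHLHE40, and biosimilar replicate 6 at 191 CPM for ERBB3. Herceptin replicate 2 was high for KREMEN2 at 2.86 CPM and, with identical counts, for RNA5-8SN3, 5_8S_rRNA and RNA5-8SN1 at 7.34 CPM.

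For the direct comparison of the antibodies, 3 lists differed by camera with the preset correlation and 0 with an estimated one. The median log2 difference, biosimilar minus Herceptin, was -0.0772 for basal and myoepithelial markers, -0.04 for hypoxia response genes and 0.0577 for mitochondrially encoded mRNAs.

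For the changes against control, no other division of the libraries tried gave as many genes. Among 100 splits of the 16 libraries compared, the real split alone did (1 of 100, the smallest share 100 splits can give). It gave 6405 genes for Herceptin, against at most 3264 in another split, with 1 library moved. For the biosimilar it gave 6178 against at most 2561. Chance differences between cultures were not tested, since nothing says that the libraries were separate cultures. For the biosimilar against Herceptin chance cannot be excluded, since 26 of 100 splits had as many genes at an unadjusted p under 0.05 as the real 764 and the highest other split had 1807.

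The cornified envelope genes of the 1q21 cluster rose with both antibodies, with a median log2 fold change of 1.34 over 7 tested genes. A copy-number difference would lift the neighbours, but 153 tested genes within 3 Mb on either side had a median of 0.0038 with Herceptin (95% bootstrap interval -0.022 to 0.0432). Keratinocytes among the cells would bring keratins, but KRT1, KRT5, KRT10 and KRT14 together rose by 0.718 CPM against 125.9 CPM for the cluster genes, with the caveat that KRT10 stood at 66.7 CPM in control. Reads shared between paralogs would leave counts that are not whole, which 14.29% of the risen genes had. A response of the cells to the antibodies remains a hypothesis, and unlabelled batches stay open.

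Mitochondrially encoded mRNAs were higher while nuclear oxidative phosphorylation mRNAs were lower. Spread between libraries would make the groups overlap, but 8 of 8 libraries of each antibody had a mitochondrial share above the highest control (3.604%). The exact permutation p was 1.55e-04 for both, the smallest the libraries can give. That p follows from the full separation and adds no further support. Bias by length, abundance or GC would lower matched genes as far, but at most 0.02% of random lists matched on these had a median as low as the 34 nuclear genes. Matched genes were drawn independently, while the 34 had an estimated inter-gene correlation of 0.33, so that this share may be too small. With an estimated correlation the list did not pass camera (adjusted p = 0.106 and 0.124). The matched lists alone thus cannot decide against such a bias. The matched lists were themselves lower, at -0.0803 with Herceptin and -0.106 with the biosimilar against -0.215 and -0.24, so that such a bias may account for part of the fall. The data do not say whether the antibodies or an unlabelled difference in handling moved the share.

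Short transcripts were lower with the biosimilar than with Herceptin: the short ribosomal protein and oxidative phosphorylation genes had a median log2 difference of -0.073. Other short genes were lower too, at -0.04984, while genes above the median length stood at 0.0112, which is consistent with a length-dependent difference between libraries. The mean short-gene score differed by -0.0764 (exact permutation p = 0.0479), but by -0.0663 over genes of at least 10 CPM (exact permutation p = 0.144). Whether a few libraries make the difference cannot be told apart: 129.2% of it was left without the 2 libraries per group farthest from the group median, but the biosimilar libraries so removed were the 2 highest over all tested genes, which oppose it, and 41.5% without the 2 lowest biosimilar and 2 highest Herceptin libraries, a removal that shrinks it by construction (85.9% and 2.85% over genes of at least 10 CPM). Against control the short-gene score differed by -0.0644 with Herceptin (exact permutation p = 0.0163) and by -0.141 with the biosimilar (exact permutation p = 0.00342). Over genes of at least 10 CPM it differed by -0.128 (exact permutation p = 7.77e-04) and -0.194 (exact permutation p = 0.00109). Lower short transcripts were thus not particular to the comparison of the antibodies. No biological explanation was tested.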

How the results depend on the processing

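Alternatives chosen after seeing the data were thinning every library to the smallest total (6056, 6332 and 0 genes for Herceptin against control, the biosimilar against control and the biosimilar against Herceptin) and leaving out the 20 most abundant and the mitochondrially encoded genes (6241, 6478 and 0).

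Counts of changed genes against control stayed within 1.5 times under the other scalings, filters and tests run, and fell where a size of change was required: to 1079 and 1197 against a 1.2-fold change and to 120 and 118 for at least 2-fold. For the biosimilar against Herceptin, DESeq2 called 8 genes, all copies of the 5.8S ribosomal RNA and all lower with the biosimilar. With no filter on low counts 12 were called, of which 11 were lower with the biosimilar and 1 was higher. The cause was not tested. The correlation of the antibodies' fold changes was 0.7471 and 0.7377 with the controls divided, which leaves 4 control libraries per antibody, and 0.9619 with at least 5 CPM in 8 libraries. With an estimated correlation 9 and 7 lists passed against control and 0 between the antibodies. With fry, which does not compare a list with other genes, 24 passed with either antibody against control and 0 between the antibodies. These 24 include lists that did not pass camera, which called 19 with Herceptin and 17 with the biosimilar. Cholesterol synthesis genes with the biosimilar passed with library totals alone (adjusted p = 0.0487 against 0.0619). ESAM, which did not pass, turned to 0.002111 with 1 surrogate variable and 0.008712 in thinned libraries with Herceptin, and to 0.002188 with upper-quartile factors and 0.002713 with at least 5 CPM in 8 libraries with the biosimilar. EGFR, biosimilar against Herceptin, turned to 0.00955 with 1 surrogate variable. The cause was not tested.

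With the replicate number as a block, 6584, 6735 and 14 genes were called, and the 14 were all lower with the biosimilar than with Herceptin. Same-numbered libraries did not deviate together: correlations of 24 pairs ran from -0.0779 to 0.102, 1 was over 0.1, and 4 libraries correlated best with their own number, so the numbers were not taken to pair the samples. The block also brought antigen presentation genes with Herceptin past the threshold (adjusted p = 0.0415 against 0.055).

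Leaving out each library in turn gave 5997 to 6244 genes for Herceptin, 6200 to 6657 for the biosimilar and 0 to 0 between the antibodies, and ERBB2 log2 fold changes of 0.1037 to 0.1207, 0.1178 to 0.1384 and 0.005103 to 0.02573. The comparison is limited for low genes: those not bounded within 1.5-fold had a median of 1.22 CPM. Whether depth is the cause was not tested.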

Other observations

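The bounds of the cluster and the look at biosimilar replicate 6 described here were chosen after the values were seen, and the test of the response size was planned.

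Beyond LCE3D, PRR9 and SPRR1B, the cluster of epidermal genes on chromosome 1 from 152084144 to 153262122 (GRCh38) held 4 other tested genes, named here after their values were seen, and all 7 rose with both antibodies. IVL, which encodes the cornified envelope protein involucrin, went from 95.88 ± 7.05 CPM in control (SD, n = 8) to 167.3 ± 3.87 with Herceptin and 156.1 ± 5.43 with the biosimilar, and TCHHL1 from 29.33 ± 1.81 to 74.18 ± 3.64 and 70.45 ± 7.41. TCHH rose by 0.99 (SE 0.109) and 0.76 (SE 0.113) on the log2 scale and SPRR3 by 1.21 (SE 0.328) and 1.34 (SE 0.328). None of the 7 passed the threshold between the antibodies, which does not show that they rose alike. Their log2 differences, biosimilar minus Herceptin, ran from -0.319 for PRR9 to 0.128 for SPRR3, and only SPRR3 was higher with the biosimilar. LCE3D, PRR9 and SPRR1B were not bounded within 1.5-fold (pair of one-sided tests, adjusted p = 0.0836, 0.0855 and 0.0574).

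A hypothesis that the biosimilar response was weaker or stronger as a whole was tested with a score along the genes that changed with Herceptin, fitted in part of the libraries and read in the held-out ones, with control at 0 and Herceptin at 1. Held-out biosimilar libraries scored 0.9888 on average, 0.977 in 1 division (exact permutation p = 0.686, n = 4) and 1 in the other (exact permutation p = 1, n = 4), where the smallest possible p was 0.0286. A difference in size was therefore not detected, which does not show that there is none. In the division at 0.977, biosimilar replicate 6 scored 0.8922 and the other biosimilar libraries 0.9913 to 1.02.

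Biosimilar replicate 6 stood apart from the other biosimilar libraries. The chi-square per degree of freedom of its 7 pairs ran from 4.261 to 7.912, against at most 4.071 between the other 7 libraries. It also had the highest short-gene score of its group, at -0.9743. Without it 6657 genes changed against control, the highest count with 1 library left out, and 0 between the antibodies. It was kept in all main tests, and why it stood apart was not tested.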
